A study of Homo sapiens with 36 samples.

How the data were processed

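RNA-seq of polyadenylated RNA from MCF7, an estrogen receptor-positive human breast cancer cell line, was measured in 36 libraries made with a stranded mRNA kit. In the first series the cells received HNRNPH1 siRNA at 7 doses or a control siRNA (8 groups, 24 libraries). In the second they received an HNRNPH1 expression plasmid in 3 amounts or an empty vector (4 groups, 12 libraries). Each group held 3 replicates, and all cells were harvested at 48 h. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

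The deposited tables hold raw counts of reads per gene, as whole numbers, with 1 column per library and no normalization by the authors. Per the submitters' processing notes, FastQC 0.11.5, STAR 2.5.4b, SAMtools 1.5, Subread 1.5.1 and featureCounts were used with genome build GRCh38.p7. The strand setting and the annotation release were not given in the sources used here. Gene symbols, positions and biotypes were looked up by Ensembl identifier in GENCODE release 44 on GRCh38, which matched 56948 of the 57992 identifiers. The protocol text describes samples that differed in RNA input, PCR cycles and sequencing pool, and their numbering seems to separate the plasmid series from the siRNA series. Each series was therefore compared only with its own control, and preparation and series cannot be told apart. Whether the total amount of siRNA or plasmid was held constant across doses is not stated.

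Total counts per library lay between 45672844 and 50211338 in the siRNA series and between 52910571 and 59941890 in the plasmid series. Between 23666 and 25819 genes had a count in the siRNA libraries, and between 25009 and 25678 in the plasmid libraries. No replicate pair looked like a copied library, with a lowest chi-square per gene of 4.79 over 36 pairs. The reads carry no molecular identifiers, so sequencing depth bounds counting error only.

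Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr on the groups (minimum count 10, minimum total count 15), which left 17823 genes in the siRNA series and 17534 in the plasmid series. TMM factors, estimateDisp, robust glmQLFit and the quasi-likelihood F test were applied to all libraries of a series, with a contrast of each dose against its control. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of its F statistic. Dose trends were fitted without control libraries, as slopes on log10 of the siRNA dose over 17741 genes and on log2 of the plasmid amount over 17341 genes. The difference between the top-dose responses of both series was fitted over all 36 libraries and 18537 genes. CPM values were scaled by the TMM factors.

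26 gene lists were fixed, covering the HNRNPH/F family, other hnRNP proteins, SR proteins, the core spliceosome, nonsense-mediated decay factors and targets, and genes with splicing tied to HNRNPH in earlier work. They also covered early estrogen response, luminal identity, mesenchymal and basal markers, p53 targets, interferon response, the integrated stress response, endoplasmic reticulum chaperones, heat shock, DNA replication and mitosis. The remaining lists were the BCL2 family, cholesterol synthesis, glycolysis and hypoxia, nuclear-encoded oxidative phosphorylation, cytosolic ribosomal proteins, mitochondrially encoded transcripts, and fibroblast, blood cell and endothelial markers. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), again with an estimated correlation, and with fry.

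Most named genes followed a rule. Outside it, CDKN1A, MX1, IFIH1, ISG20, HSPA5, ESR1, PGR and CCND1 at 10 nM siRNA and NUPR1 and SESN1 at 2500 ng plasmid were chosen as examples from their lists after their values were seen. The rule took the 5 HNRNPH/F family genes in every comparison. At 10 nM siRNA and 2500 ng plasmid it took the 8 highest and 8 lowest fold changes among protein-coding genes past the threshold, with a mean of at least 5 CPM and all treated libraries on 1 side of all controls. It also took up to 2 members per list with the smallest adjusted p, the 5 rising and 5 falling genes with the smallest p in each trend, and 5 genes per direction among those called in both series, each with a mean of at least 5 CPM. The lists, the rule, the comparisons and the other settings, apart from leaving out a replicate number, were chosen before the data were examined.

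The alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, a fit without robust estimation, a replicate block, only the 2 compared groups in the fit, a linear dose or a dose rank with controls, an adjusted p under 0.01 for the overlap, and leaving out each library in turn. Leaving out each replicate number in every group was added after seeing the data. The target sequence of the HNRNPH1 siRNA was searched in the genome and in GENCODE transcripts. Splicing was not analysed, because the tables hold counts per gene.

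The tests were tried on simulated data with known changes in 67, 67 and 66 genes at log2 changes of 0.5, 1 and 2. Far fewer genes changed there than were called in the real data at 10 nM siRNA. The adjusted threshold depends on that share, so the recovery below does not carry over to that comparison. At 10 nM siRNA (17823 genes) 37.3%, 73.1% and 87.9% were recovered, with 3 false calls among 135. At 2500 ng plasmid (17534 genes) 59.7%, 83.6% and 97% were recovered, with 11 false calls among 171. For the dose trends the changes were slopes, per 10-fold siRNA dose or per doubling of plasmid. Recovery there cannot be compared with that of 2 groups. The siRNA dose trend (17741 genes) recovered 82.1%, 95.5% and 100%, with 8 false calls among 193. The plasmid dose trend (17341 genes) recovered 86.6%, 100% and 100%, with 23 false calls among 214. The difference between both series (18537 genes) recovered 26.9%, 61.2% and 84.8%, with 7 false calls among 122.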

Results

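Gene-level RNA-seq counts were collected from MCF7 cells in which HNRNPH1, an RNA-binding splicing regulator, was lowered with siRNA or raised with a plasmid. The siRNA series held a control siRNA and doses of 50, 100, 250, 500, 1000, 5000 and 10000 pM (0.05 to 10 nM). The plasmid series held an empty vector and 600, 1000 and 2500 ng of plasmid. Each of the 12 groups had 3 replicates (n = 3 for each value below). Libraries held 45672844 to 50211338 counts in the siRNA series and 52910571 to 59941890 in the plasmid series. The study was designed to follow graded HNRNPH levels, and the comparisons below ask which genes changed in abundance at each dose. Levels are given in CPM ± SD, and log2 fold changes against the series' own control ± SE, with adjusted p from edgeR's quasi-likelihood test with the Benjamini-Hochberg method.

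HNRNPH1 RNA (ENSG00000169045, GRCh38 chromosome 5, 179614178 to 179634784, minus strand) passed the test for a fall only at the 2 highest siRNA doses. It stood at 547 ± 50.7 CPM with control siRNA, 494.8 ± 58.7 CPM at 500 pM and 401.7 ± 65 CPM at 1 nM. At 5 nM it was 237.7 ± 119 CPM, or 43.5% of control (log2 -1.20 ± 0.361, adjusted p = 0.0188), and at 10 nM 241.5 ± 129 CPM, or 44.1% (log2 -1.18 ± 0.361, adjusted p = 0.0151). Each of the 3 libraries at 5 nM and at 10 nM lay below every control library. At 1 nM the log2 value was -0.45 ± 0.356, which did not pass (adjusted p = 0.782). Its libraries (358.5 to 476.4 CPM) nevertheless also lay below every control library (499.3 to 600.2 CPM). The SE at each dose rests on a spread fitted over all 8 groups, including the wide spread at 5 and 10 nM. The siRNA target GGAGCTGGCTTTGAGAGGA occurred once in the genome, at chromosome 5, 179618169 to 179618187, in coding sequence of exon 6 of HNRNPH1. Replicate 3 had the lowest HNRNPH1 level at both doses, 105.8 CPM at 5 nM and 103.2 CPM at 10 nM, and fewer genes with a count (23666 and 24016). Without the 10 nM replicate 3 the call was lost (log2 -0.83, adjusted p = 0.0531). At 5 nM it was lost without the 5 nM replicate 3 (-0.86, adjusted p = 0.0706) and without control replicate 1 (-1.14, adjusted p = 0.0564). With only the 2 groups in the fit neither dose passed (adjusted p = 0.0962 and 0.105).

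**Figure D1:**
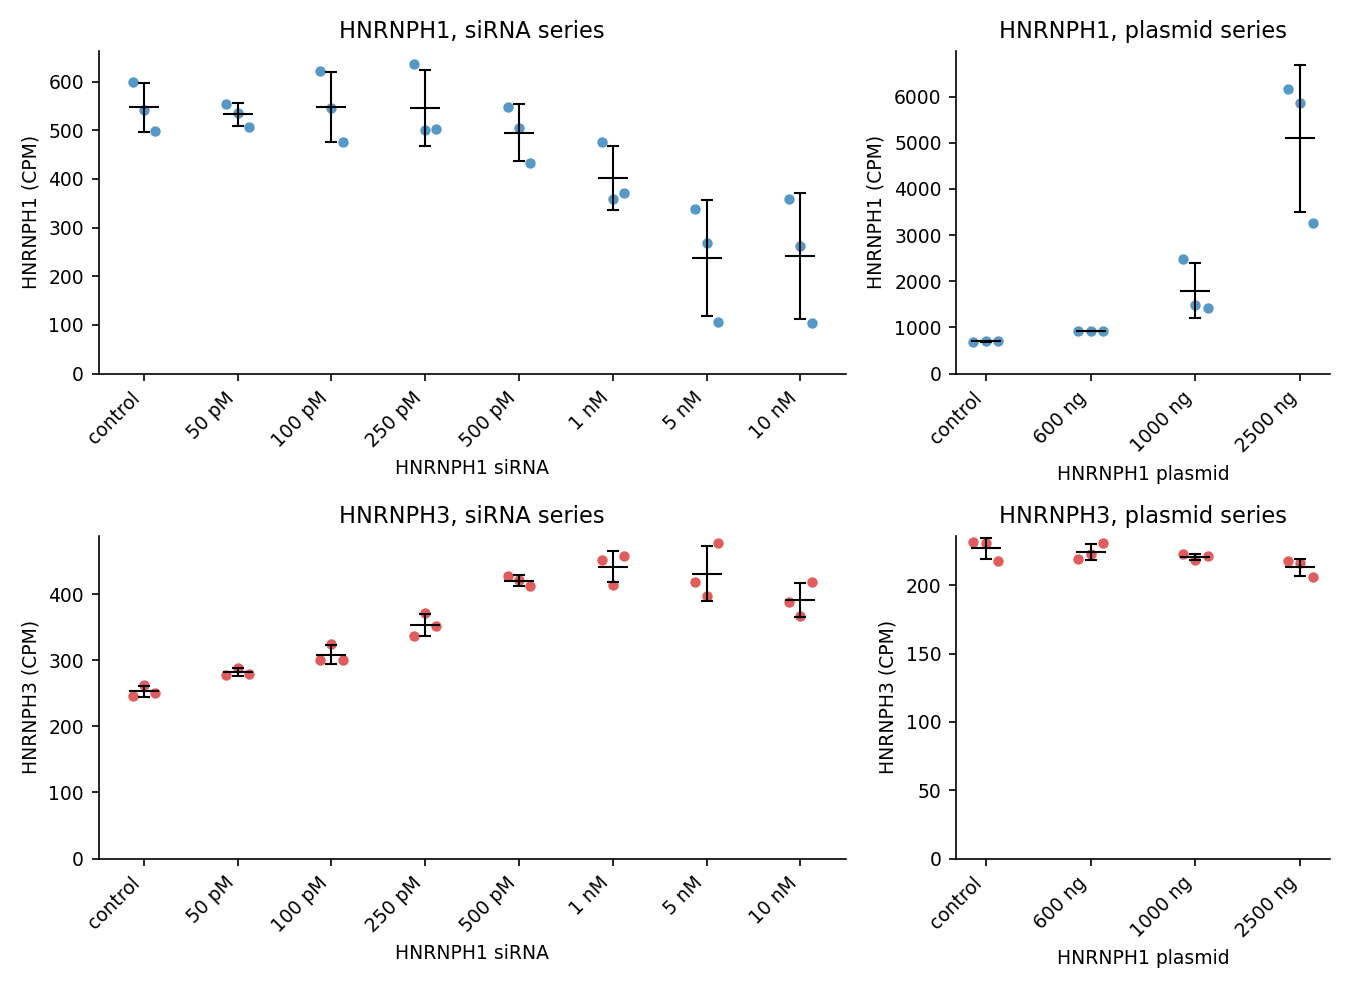
HNRNPH1 (top) and HNRNPH3 (bottom) in CPM for each library of the siRNA series (left) and the plasmid series (right), by dose; points are libraries, and bars give the mean ± SD of 3 replicates. HNRNPH1 averaged 547 CPM with control siRNA and 241.5 CPM at 10 nM, while HNRNPH3 averaged 253.1 CPM with control siRNA and 441.6 CPM at 1 nM.

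The close relative HNRNPH3 (ENSG00000096746, chromosome 10, 68331174 to 68343193, plus strand) passed the test for a rise from 250 pM of siRNA upward. It averaged 253.1 ± 8.12 CPM with control siRNA, 353.5 ± 16.9 CPM at 250 pM (log2 0.48 ± 0.069, adjusted p = 0.00435), 420.5 ± 8.13 CPM at 500 pM and 441.6 ± 23.5 CPM at 1 nM (0.80, adjusted p = 6.06e-07). At 10 nM it was 391.3 ± 25.5 CPM (0.63, adjusted p = 1.88e-07). At 50 pM (282 ± 6.12 CPM) and 100 pM (308.5 ± 14.4 CPM) it did not pass, although every library lay above every control library. The unadjusted p of edgeR's quasi-likelihood test was 0.033 at 50 pM and 0.00041 at 100 pM. At 250 pM HNRNPH1 itself averaged 546.6 ± 78.1 CPM. The HNRNPH3 call at 250 pM was lost without control replicates 1 or 3 or the 250 pM replicate 2 (adjusted p from 0.0743 to 0.114). HNRNPH2, which is nearly identical to HNRNPH1 in sequence, fell slightly at 10 nM (log2 -0.18 ± 0.071, adjusted p = 0.0494), a call that DESeq2 did not make (adjusted p = 0.055) and that was lost without any 1 of the libraries of these groups except the 10 nM replicate 3. HNRNPF (0.15, adjusted p = 0.197) and GRSF1 (0.06, adjusted p = 0.41) did not pass at 10 nM. Of the 5 family members tested, 1 rose and 2 fell, as also when adjusted over the list alone, and the list did not pass camera (median log2 0.06, mean -0.11, adjusted p = 0.748).

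At 50 and 100 pM no gene passed in edgeR (0 and 0) or DESeq2 (0 and 0), with 255 and 270 genes at an unadjusted p under 0.05. At 250 pM 2 genes rose, HNRNPH3 and SERINC2, a serine incorporator family member (log2 0.78 ± 0.095, adjusted p = 0.000657). DESeq2 called 3, adding GALE. At 500 pM 39 genes rose and 65 fell, and at 1 nM 95 rose and 174 fell. Several genes moved stepwise. SERINC2 stood at 1.06 at 500 pM, 1.38 at 1 nM and 1.86 at 10 nM. GALE, the UDP-galactose epimerase, stood at -0.93, -1.08 and -1.82, and SFXN2, a mitochondrial sideroflexin, at -0.57, -0.83 and -1.62. RBM3, a cold-inducible RNA-binding protein, stood at -0.88 (adjusted p = 0.0422), -1.09 and -1.49. Without the filter on low counts 16 genes passed at 100 pM and 28 at 250 pM. The 250 pM count was 4 with only the 2 groups in the fit, and 1 without control replicate 1, control replicate 3 or the 250 pM replicate 2. The 500 pM count was 24, 27 and 19 without control replicates 1, 2 and 3, 16 without the 500 pM replicate 2 and 347 without the 500 pM replicate 1. It was 449 with DESeq2, 693 with a replicate block, 278 without the filter on low counts and 5 with only the 2 groups in the fit. Without the replicates numbered 1, 2 and 3 in every group it was 5, 4 and 10. The 1 nM count was 112, 114 and 111 without control replicates 1, 2 and 3, and 124, 97 and 142 without the 1 nM replicates 1, 2 and 3. It was 501 with a replicate block, and 17, 9 and 83 without the replicates numbered 1, 2 and 3 in every group.

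**Figure D2:**
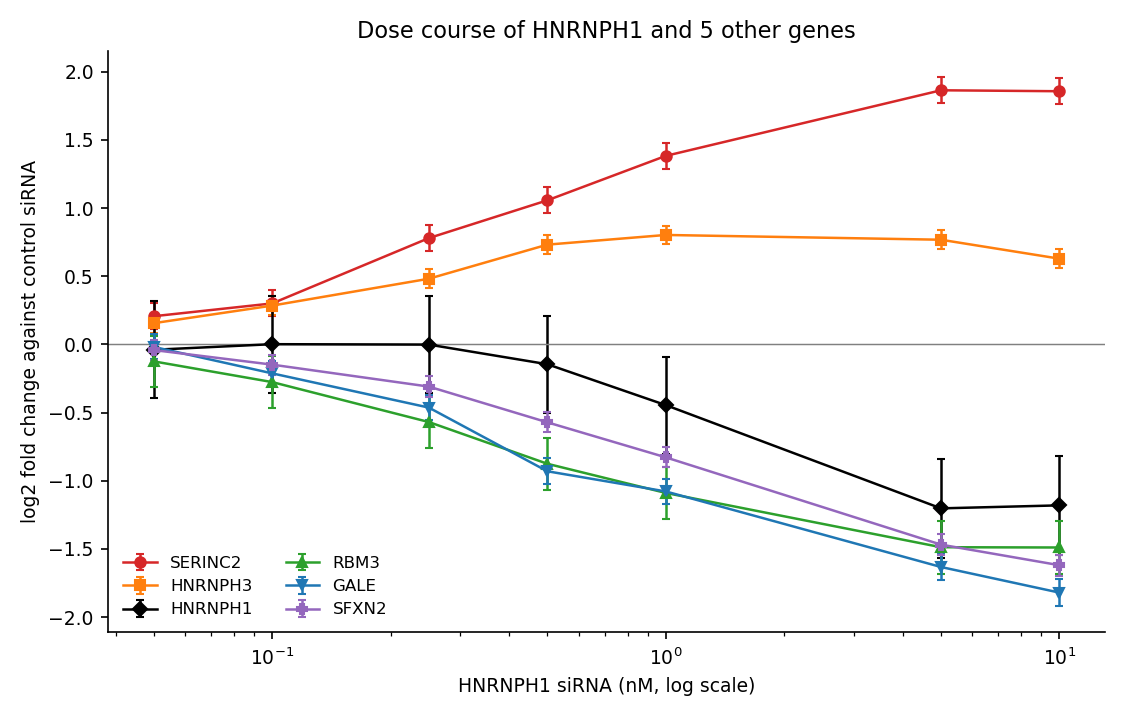
Log2 fold change against control siRNA (vertical axis) by HNRNPH1 siRNA dose in nM (horizontal, log scale) for HNRNPH1 and 5 other genes; points are fitted values from 3 replicates per dose and bars are ± SE. SERINC2 reached 1.86 and GALE -1.82 at 10 nM, and at 500 pM both had passed the test while HNRNPH1 (-0.145 ± 0.356), with its wide error, had not.

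At 5 nM 4854 of 17823 genes passed (2643 rose, 2211 fell), and at 10 nM 6704, or 37.6% (3464 rose, 3240 fell). The 5 nM count was 3400 with only the 2 groups in the fit. Without the replicates numbered 1, 2 and 3 in every group the 10 nM count was 5199, 4435 and 5349. At 10 nM 544 genes rose and 443 fell by at least 2-fold. Among protein-coding genes averaging at least 5 CPM, the strongest rise was in PRRT4, a proline-rich transmembrane protein gene (ENSG00000224940), at 16.01 ± 0.594 CPM against 1.22 ± 0.237 (13.1-fold, log2 3.71 ± 0.188, adjusted p = 2.6e-12). SEMA7A, a membrane-anchored semaphorin (2.21 ± 0.129), KRT86, a hair keratin (2.01), TRIM71, a developmental RNA-binding ubiquitin ligase (1.99), and MAB21L4 (1.97) followed. GABBR2, a GABA-B receptor subunit (1.95), SLC22A17, a lipocalin receptor (1.94), and FOLR1, folate receptor alpha (1.90), also rose. The deepest fall among such genes was in the interferon-induced IFI44L (24.1% of control, log2 -2.05 ± 0.219, adjusted p = 2.71e-07). SWAP70, a Rac signalling protein (-1.87 ± 0.073), SULF1, an extracellular heparan sulfatase (-1.87), and ASCL1, a neurogenic transcription factor (-1.80), fell with GALE (-1.82). FRK, a Src-related kinase (-1.75), LAMP3, a lysosomal membrane protein (-1.74), and FBXL16, an F-box protein (-1.72), fell as well. The 16 genes were picked with all 3 treated libraries on 1 side of all 3 controls, so that separation is no finding. KRT86 has close paralogs, so its reads may be shared.

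**Figure D3:**
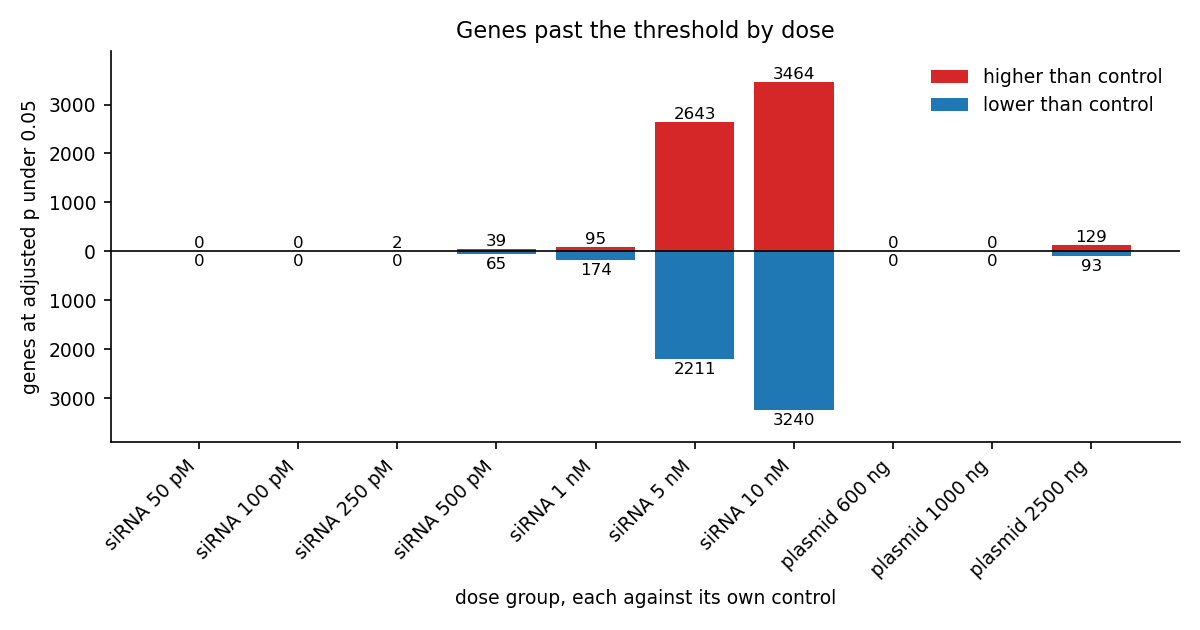
Number of genes at an adjusted p under 0.05 (vertical axis) for each dose group against its own control (horizontal axis, n = 3 per group); bars above 0 count genes that rose and bars below 0 genes that fell. The counts climbed from 0 at 50 and 100 pM to 6704 at 10 nM siRNA, while only the 2500 ng group of the plasmid series had genes past the threshold (222).

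Cell cycle genes fell at 10 nM siRNA. Member counts at this dose stand against a background of 3219 risen and 2763 fallen among 13820 protein-coding genes tested. Of 30 DNA replication genes 26 fell and 0 rose (28 fell and 1 rose adjusted over the list alone; median log2 -0.44), among them CDC45 (-0.94 ± 0.065) and MCM3 (-0.79 ± 0.056), parts of the replicative helicase. The list passed camera (adjusted p = 4.33e-12), but not with an estimated correlation (adjusted p = 0.163 with an estimated correlation). Of 29 mitosis genes 23 fell (26 adjusted over the list alone; median -0.31), among them TPX2, a spindle factor (-0.86), and AURKB, a mitotic kinase (-0.72), with adjusted p = 7.16e-09 and adjusted p = 0.163 with an estimated correlation. p53 targets went both ways, with 4 risen and 10 fallen of 23 (4 and 11 adjusted over the list alone; median -0.17). DDB2, a DNA repair factor (-0.83), SPATA18 (-1.22) and the cell cycle inhibitor CDKN1A (-1.16) fell, and TNFRSF10B, a TRAIL receptor (0.43), rose. That list passed at adjusted p = 0.0415, with adjusted p = 0.171 with an estimated correlation. At 5 nM 20 replication and 22 mitosis genes fell, and at 1 nM 2 and 0.

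The interferon list fell most. Of 32 tested members 28 fell, 1 rose and 3 did not pass at 10 nM (29 fell and 1 rose adjusted over the list alone), with a median log2 of -1.02. Beside IFI44L, the helicase gene DDX60 (-1.70 ± 0.226), the antiviral GTPase gene MX1 (-1.16) and the RNA sensor gene IFIH1 (-1.03) fell, while the exonuclease gene ISG20 rose (0.40). The list passed camera (adjusted p = 7.16e-09), but had adjusted p = 0.48 with an estimated correlation. At 5 nM 12 members fell and 1 rose (median -0.54), and at doses up to 1 nM 0 passed in either direction. Without the replicates numbered 2 in every group 14 members fell at 10 nM (median -0.80) and 3 at 5 nM. Without those numbered 3, 25 fell at 10 nM and 7 at 5 nM.

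Endoplasmic reticulum chaperones rose, 14 of 15 with 0 fallen, both over all genes and adjusted over the list alone (median 0.41). Examples were DNAJB9, a luminal cochaperone (0.99 ± 0.122), HERPUD1, a degradation factor (0.59 ± 0.066), and HSPA5, the main luminal chaperone (0.29). Camera gave adjusted p = 1.56e-06, and adjusted p = 0.246 with an estimated correlation. Of 17 luminal identity genes 9 rose and 1 fell (9 and 2 adjusted over the list alone; median 0.31), with adjusted p = 0.0428 and adjusted p = 0.48 with an estimated correlation. CDH1, E-cadherin (0.66), and CLDN4, a claudin of tight junctions (1.02), rose, and ESR1, estrogen receptor alpha, fell (-0.44). The early estrogen response split, with 11 risen and 7 fallen of 29 (12 and 7 adjusted over the list alone; adjusted p = 0.103). CA12, a carbonic anhydrase (0.98), and KCNK5, a potassium channel (1.63), rose, and the progesterone receptor gene PGR (-0.76) and cyclin D1 gene CCND1 (-0.66) fell. Mesenchymal and basal markers had 3 risen and 6 fallen of 12 (4 and 6 adjusted over the list alone; adjusted p = 0.579), with KRT17, a keratin, up (1.12) and TP63, a p63 transcription factor, down (-0.86).

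RNA-processing genes fell in part at 10 nM, where 2763 of all 13820 protein-coding genes tested also fell and 3219 rose. Among 24 other hnRNP genes 9 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.12), with HNRNPA3 at -0.63 ± 0.059 and HNRNPM at -0.51 (adjusted p = 0.021, and adjusted p = 0.497 with an estimated correlation). Of 32 core spliceosome genes 10 fell and 0 rose, also adjusted over the list alone. The helicase genes SNRNP200 (-0.56) and DHX15 (-0.35) were among them (adjusted p = 0.0415, and adjusted p = 0.744 with an estimated correlation). Of 16 nonsense-mediated decay factors 7 fell and 1 rose, also adjusted over the list alone, with SMG5 at -0.81 and the endonuclease gene SMG6 at -0.56 (adjusted p = 0.0484, and adjusted p = 0.479 with an estimated correlation). Targets of that pathway had 1 risen (TNFRSF10B) and 3 fallen of 16, among them SNHG8 (-0.36), and did not pass (1 and 3 adjusted over the list alone; adjusted p = 0.83). SR protein genes had 1 risen (SRSF9, 0.28) and 2 fallen of 13, with SRSF1 at -0.38 (1 and 1 adjusted over the list alone; adjusted p = 0.659). Of 14 genes with splicing tied to HNRNPH in earlier work 3 rose and 6 fell (4 and 6 adjusted over the list alone; adjusted p = 0.83). The receptor kinase gene ERBB2 (0.97 ± 0.085) and the proapoptotic BCL2L11 (0.60) rose. In that list the median was -0.07 and the mean 0.04, with a downward camera direction.

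Stress and metabolic lists were mixed at 10 nM. The integrated stress response had 3 risen and 6 fallen of 16 (4 and 8 adjusted over the list alone; adjusted p = 0.483), with NUPR1, a stress-induced nuclear protein (-1.20), and SESN2, a sestrin (-0.56), down. Heat shock genes had 1 risen and 4 fallen of 12 (1 and 6 adjusted over the list alone; adjusted p = 0.116), with HSPA1A at -0.47 and its near-identical paralog HSPA1B at -0.36, whose reads may be shared. The BCL2 family had 8 risen and 7 fallen of 25 (8 and 9 adjusted over the list alone; adjusted p = 0.943, downward with a mean of 0.02), with DIABLO at -0.76. Cholesterol synthesis had 9 risen and 5 fallen of 22 (10 and 5 adjusted over the list alone; adjusted p = 0.272), and the pathway enzyme genes FDPS (-0.50) and LSS (-0.42) fell. Glycolysis and hypoxia genes had 8 risen and 5 fallen of 27, also adjusted over the list alone (adjusted p = 0.579), with ALDOC, an aldolase, at 1.16 and NDRG1 at 0.63. Oxidative phosphorylation had 5 risen and 1 fallen of 31 (4 and 0 adjusted over the list alone; adjusted p = 0.659), with NDUFA4 at 0.47 and COX6C at 0.37.

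Ribosomal protein genes had 4 risen and 0 fallen of 46 at 10 nM (0 and 0 adjusted over the list alone; median 0.17), with adjusted p = 0.0484 and adjusted p = 0.887 with an estimated correlation. RPLP1 (0.40) was lost without the 10 nM replicate 3 (adjusted p = 0.0747). RPS18 (0.41) was lost without control replicates 1 or 2 or the 10 nM replicates 2 or 3 (highest adjusted p = 0.136), and both genes have many processed pseudogenes. The share of counts from mitochondrially encoded genes, which can follow RNA quality, was 4.41 ± 1.01% in controls, 5.6 ± 1.86% at 5 nM and 6.09 ± 3.11% at 10 nM. None of the 13 listed mitochondrially encoded genes passed in edgeR over all genes or adjusted over the list alone (0 and 0; median 0.41; adjusted p = 0.579). Outside that list the mitochondrial ribosomal RNA gene MT-RNR2, chosen after its values were seen, rose (1.13 ± 0.317, adjusted p = 0.00831), and MT-RNR1 did not pass (0.70, adjusted p = 0.141). By fry, which tests a list without reference to other genes, the ribosomal list did not pass (adjusted p = 0.289). At 10 nM fry alone passed the HNRNPH/F family (adjusted p = 0.0368), the early estrogen response (0.00162), the integrated stress response (0.023), heat shock genes (0.0156) and endothelial markers (0.000265). The fry direction of the family list was upward, though the list holds the siRNA target HNRNPH1, which fell. Markers of other cell types were few. Of 4 fibroblast markers 1 rose (0 adjusted over the list alone; too few to test), PDGFRB, at 0.21 CPM, a call lost without 5 of the 6 libraries, all but control replicate 1 (highest adjusted p = 0.175). Of 5 blood cell markers 0 passed, also adjusted over the list alone (adjusted p = 0.739). Of 5 endothelial markers 2 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.483), with VWF at 1.97 CPM (1.34) and ERG at 2.99 CPM (0.96).

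**Figure D4:**
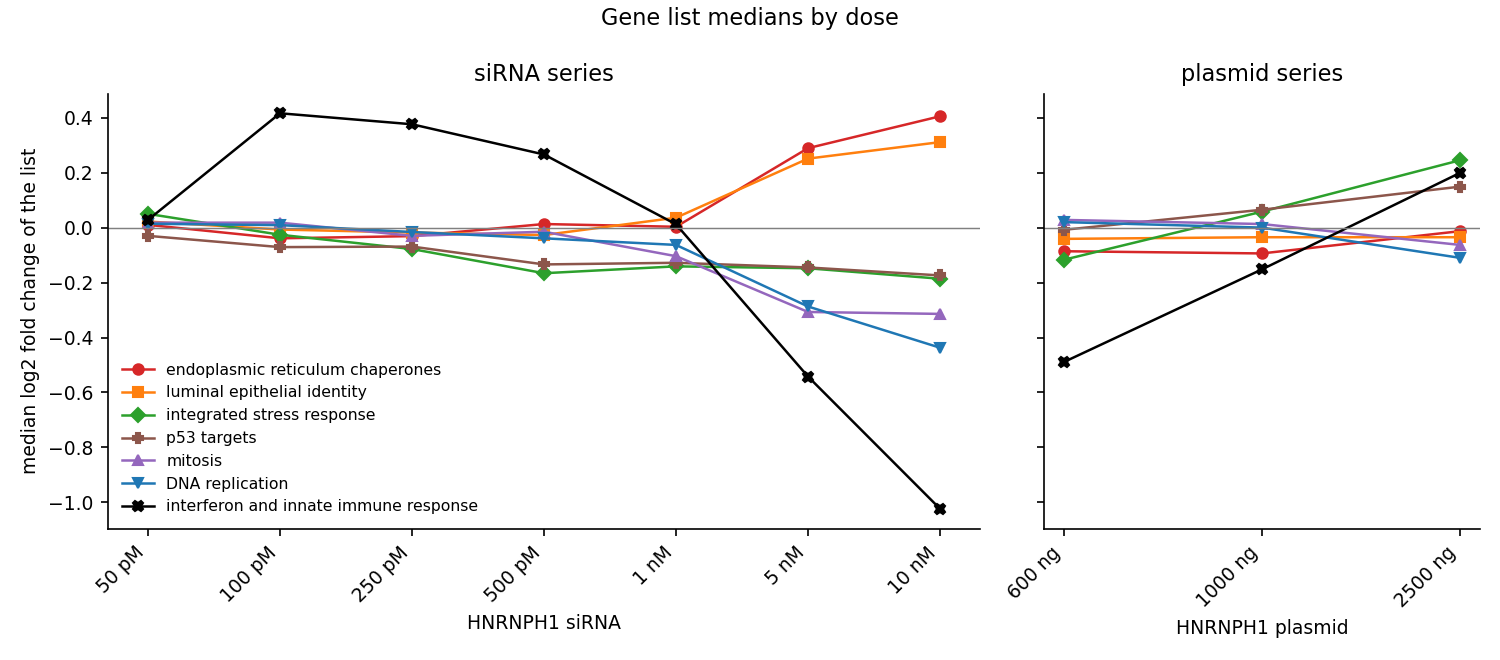
Median log2 fold change against the series' own control (vertical axis) of 7 gene lists by dose (horizontal axis) in the siRNA series (left) and the plasmid series (right); each point is the median over the tested genes of a list, with 3 replicates per group. At 10 nM siRNA the interferon list lay at -1.02 and endoplasmic reticulum chaperones at 0.41, and at 2500 ng plasmid the integrated stress response lay at 0.25.

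The trend over the 21 libraries with HNRNPH1 siRNA asks which genes followed the dose without use of the control. It called 8327 of 17741 genes (4367 rose, 3960 fell; 46.9%). HNRNPH1 changed by -0.60 ± 0.129 log2 per 10-fold dose (adjusted p = 0.000591), HNRNPH2 by -0.09 (adjusted p = 0.0124) and HNRNPH3 by 0.23 ± 0.045 (adjusted p = 0.000145). Among genes averaging at least 5 CPM, the smallest p among risers were in the long noncoding RNA gene ENSG00000261888 (1.01 ± 0.047), SERINC2 (0.79), GABBR2 (1.03), TNS1, a focal adhesion protein gene (0.54), and TGFB3, a growth factor gene (0.49). The smallest p among fallers were in GALE (-0.81 ± 0.036), SFXN2 (-0.73), the coenzyme Q synthesis gene COQ9 (-0.55), PNPO, which makes active vitamin B6 (-0.40), and the RNA-binding protein gene TAF15 (-0.43). The adjusted p of these 10 genes lay between 4.28e-14 and 1.4e-11, and leaving out any 1 of the 21 libraries lost none of the 10 calls.

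In the plasmid series HNRNPH1 counts include plasmid and endogenous transcripts. They rose from 700.6 ± 9.89 CPM with empty vector to 5098 ± 1600 CPM at 2500 ng (7.28-fold, log2 2.86 ± 0.263, adjusted p = 0.00123). At 600 ng the mean was 919.7 ± 5.13 CPM (0.39, adjusted p = 0.9998) and at 1000 ng 1795 ± 600 CPM (1.36 ± 0.25, adjusted p = 0.625; DESeq2 adjusted p = 0.00495), with all 3 libraries above all 3 controls at each amount. The edgeR test at each amount used a spread fitted over all 4 groups, including the wide spread at 1000 and 2500 ng. HNRNPH3 (-0.09, adjusted p = 0.276), HNRNPH2 (-0.00), HNRNPF (-0.03) and GRSF1 (-0.06) did not pass at 2500 ng, so 1 of the 5 family members rose (1 adjusted over the list alone; adjusted p = 0.912; median -0.03, mean 0.54). At 600 ng 0 genes passed in edgeR, with 770 at an unadjusted p under 0.05, DESeq2 called 114, and edgeR called 22 without empty-vector replicate 2, 203 without the filter on low counts and 21 with only the 2 groups in the fit. At 1000 ng 0 passed in edgeR, with 1238 at an unadjusted p under 0.05. DESeq2 called 4, which were HNRNPH1, TPBG, KISS1R and RBM3, of which KISS1R was chosen after its values were seen.

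At 2500 ng 129 genes rose and 93 fell, 19 and 0 of them by at least 2-fold. After HNRNPH1 the largest rises among protein-coding genes averaging at least 5 CPM were in SLC7A11, the cystine transporter (12.71 ± 1.73 to 26.33 ± 3.98 CPM, log2 1.05 ± 0.148, adjusted p = 0.00963), and the aldo-keto reductase genes AKR1C3 (0.91 ± 0.103) and AKR1C2 (0.75 ± 0.088), paralogs that may share reads. GBP1, a guanylate-binding protein (0.78), TNFAIP3, an inhibitor of NF-kappaB signalling (0.77), DDIT3, the stress factor CHOP (0.75), and PLAAT4 (0.71) rose too. The largest falls among such genes were in ACO1, the iron-regulated cytosolic aconitase (-0.54 ± 0.074, adjusted p = 0.00433), ELMOD2 (-0.38), FITM2, a lipid droplet factor (-0.36), and SLC16A2, a thyroid hormone transporter (-0.35). OLFML2A (-0.35), BRI3BP (-0.34), TSPAN1, a tetraspanin (-0.34), and SLC39A8, a metal ion transporter (-0.33), also fell. KISS1R, a kisspeptin receptor gene below that level and chosen after its values were seen, rose more (4.86 ± 0.437, adjusted p = 0.000632). The count was 27, 40 and 116 without the 2500 ng replicates 1, 2 and 3, and 124 and 30 without empty-vector replicates 2 and 3. It was 454 with DESeq2, 629 without the filter on low counts and 58 with only the 2 groups in the fit. Among genes tested in both series, 3, 0 and 51 passed without the replicates numbered 1, 2 and 3 in every group, against 216 over all libraries. Of 32 named genes 9 kept their call without each single library: HNRNPH1, AKR1C3, AKR1C2, ACO1, ELMOD2, CREBRF, SAT1, RBM3 and the p53 target TP53INP1. SLC7A11 and GBP1 were lost without the 2500 ng replicate 1 or empty-vector replicate 3 (highest adjusted p = 0.0542 and 0.0665), and TNFAIP3 and DDIT3 also without the 2500 ng replicate 2 (0.0743 and 0.0867). PLAAT4 was lost without any 1 library except the 2500 ng replicate 2 (highest 0.170), FITM2 without the 2500 ng replicate 2 (0.0556) and BRI3BP without that or the 2500 ng replicate 1 (0.0565). OLFML2A and TSPAN1 were lost without any 1 library except empty-vector replicate 1 (highest 0.124 and 0.118). SLC16A2 was lost without the 2500 ng replicates 1 or 2 or empty-vector replicate 3 (highest 0.0784), and SLC39A8 also without the 2500 ng replicate 3 (0.0884).

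Of 16 integrated stress response genes 3 rose and 0 fell at 2500 ng (11 and 0 adjusted over the list alone; median 0.25), SLC7A11, DDIT3 and NUPR1 (0.93 ± 0.206), with adjusted p = 8.72e-10 and adjusted p = 0.178 with an estimated correlation. Of 23 p53 targets 3 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.15): TP53INP1 (0.41 ± 0.046), the antiproliferative BTG2 (0.53) and SESN1 (0.21), with adjusted p = 6.21e-07 and adjusted p = 0.178 with an estimated correlation. NUPR1 and SESN1 were not tested with libraries left out, and BTG2 was lost without the 2500 ng replicates 1 or 2 or empty-vector replicates 2 or 3 (highest adjusted p = 0.0899). In the BCL2 family PMAIP1, the proapoptotic NOXA (0.31), rose alone of 25 (1 adjusted over the list alone; adjusted p = 0.00325, and adjusted p = 0.178 with an estimated correlation). It was lost without the 2500 ng replicates 1 or 2 or empty-vector replicate 3 (highest adjusted p = 0.0743). The interferon list had 0 of 32 past the test in edgeR over all genes and 5 risen adjusted over the list alone (median 0.20; adjusted p = 3.12e-08, and adjusted p = 0.371 with an estimated correlation).

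DNA replication genes had 1 fallen of 30 (14 adjusted over the list alone; median -0.11), CDC45 (-0.18 ± 0.038), with adjusted p = 4.19e-11 and adjusted p = 0.178 with an estimated correlation. The CDC45 call was lost without any 1 of the 6 libraries (highest adjusted p = 0.155). Mitosis genes had 0 past the test (0 adjusted over the list alone; adjusted p = 0.00299, and adjusted p = 0.371 with an estimated correlation), and cholesterol synthesis 0 of 22 (3 fallen adjusted over the list alone; adjusted p = 0.00562, and adjusted p = 0.371 with an estimated correlation). The early estrogen list had 2 fallen of 29 (4 adjusted over the list alone; adjusted p = 0.0376, and adjusted p = 0.371 with an estimated correlation), the trophoblast glycoprotein gene TPBG (-0.22) and the receptor kinase gene RET (-0.31). TPBG was lost without empty-vector replicate 3 (adjusted p = 0.0502), and RET without that library or the 2500 ng replicates 1 or 2 (highest 0.0583). Oxidative phosphorylation genes leaned downward (median -0.06; adjusted p = 0.00204, and adjusted p = 0.452 with an estimated correlation), with 1 risen of 31 (1 adjusted over the list alone), NDUFV2 (0.63), a call lost without any 1 of the 6 libraries (highest 0.139). The mitochondrially encoded genes had 0 of 13 past the test over all genes and 8 fallen adjusted over the list alone (median -0.20; adjusted p = 2.41e-06, and adjusted p = 0.371 with an estimated correlation). Their share of counts was 7.67 ± 0.29% with empty vector and 6.82 ± 0.35% at 2500 ng.

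The other lists did not pass camera at 2500 ng, where fry alone passed the HNRNPH/F family, nonsense-mediated decay factors and mesenchymal and basal markers (adjusted p = 0.0459 each). The family list holds HNRNPH1, the gene raised by the plasmid, and its 4 other members did not pass, so that result is no separate finding. Of the lists past camera, fry did not pass the early estrogen response and cholesterol synthesis (adjusted p = 0.102 each), interferon and mitosis (0.126 each), mitochondrially encoded genes (0.109) and oxidative phosphorylation (0.192). Mesenchymal and basal markers had 1 risen of 10 (1 adjusted over the list alone; adjusted p = 0.146), KRT17 at 1.23 CPM (0.78), lost without any 1 library (highest adjusted p = 0.126). Glycolysis and hypoxia had 1 fallen of 27 (1 adjusted over the list alone; adjusted p = 0.146), the hexokinase gene HK1 (-0.16), lost without any 1 library except empty-vector replicate 2 (highest 0.182). With 0 members past the test over all genes stood other hnRNP proteins (0 adjusted over the list alone; adjusted p = 0.801), SR proteins (0; 0.615), the core spliceosome (0; 0.426), decay factors (0; 0.146) and decay targets (2 risen adjusted over the list alone; 0.146). The same held for genes with splicing tied to HNRNPH (0; 0.803, median 0.00 and mean -0.01), luminal identity (1 fallen adjusted over the list alone; 0.146), endoplasmic reticulum chaperones (1 risen adjusted over the list alone; 0.965, with median -0.01 and mean 0.01) and heat shock genes (0; 0.577). Ribosomal protein genes (0; 0.701, median -0.01 and mean 0.00), blood cell markers (0 of 7; 0.26), fibroblast markers (0 of 3) and endothelial markers (0 of 4) had none past the test either, the last 2 too few to test.

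The plasmid dose trend over 9 libraries called 1192 of 17341 genes (774 rose, 418 fell). HNRNPH1 changed by 1.19 ± 0.125 log2 per doubling of plasmid (adjusted p = 0.000764). Among genes averaging at least 5 CPM, the smallest p among risers were in WARS1, a tryptophanyl-tRNA synthetase (0.26 ± 0.02), OPTN, an autophagy receptor (0.46), CREBRF, a CREB3 regulator (0.35), IFI27, an interferon-induced gene (0.43), and LGALS9, a galectin (0.49), each with adjusted p = 2.66e-05. The smallest p among fallers were in ACO1 (-0.43 ± 0.035), BRI3BP (-0.21), FITM2 (-0.21), SLC39A8 (-0.19) and ATPSCKMT, a mitochondrial methyltransferase gene (-0.19), with adjusted p up to 0.000346. For all 10 genes the empty vector lay between 600 and 2500 ng, as for OPTN (-0.49 at 600 ng, adjusted p = 0.0551, and 0.48 at 2500 ng, adjusted p = 0.0035) and ACO1 (0.33, adjusted p = 0.133, and -0.54). All 10 calls were kept without each of the 9 libraries. With dose ranks that include the empty vector 7 were lost, WARS1, OPTN, CREBRF, IFI27, LGALS9, ACO1 and ATPSCKMT (adjusted p from 0.0897 to 0.377), and BRI3BP, FITM2 and SLC39A8 were kept. The count was 1791 without the 1000 ng replicate 1, 574 and 668 without the 2500 ng replicates 1 and 2, and 706 and 757 without the 600 ng replicates 2 and 3. It was 215 with dose ranks that include the empty vector, and 255 and 564 without the replicates numbered 2 and 3.

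Whether lowering and raising HNRNPH1 moved the same genes was asked over 16746 genes tested in both series. At the top doses 126 were called in both, against 83.2 expected (Fisher's exact test, p = 3.45e-09), 71 in opposite directions and 55 in the same direction. The opposite movers include HNRNPH1, the gene that was manipulated. This test and the test of direction below treat genes as independent, which they are not, so their p-values are descriptive. Opposite movers included SAT1, a polyamine acetyltransferase (-1.01 with siRNA, 0.41 with plasmid), RBM3 (-1.49, 0.36), ELMOD2 (0.53, -0.38), FITM2 (0.47, -0.36) and CPE, carboxypeptidase E (0.40, -0.31). Same-direction genes included CREBRF (0.88, 0.49), AKR1C2 (0.36, 0.75), ESYT1, a membrane tether (-0.30, -0.23), GNPDA1, an amino sugar deaminase (0.55, 0.27), and ERRFI1, an EGFR inhibitor (0.60, 0.35). Opposite against same direction did not differ from independence (2-sided Fisher's exact test, p = 0.136). The same Fisher's exact test gave p = 0.00114 with the DESeq2 calls, p = 0.0401 with a replicate block and p = 3.68e-08 without the filter on low counts. The unfiltered fit gave implausibly small p-values for HNRNPH1, so little weight rests on its calls. Across genes, which are not independent replicates, Spearman's rho of both fold changes was -0.10 and Pearson's r -0.07.

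Counts of shared genes moved with single plasmid libraries. The opposite and same counts were 6 and 7 without the 2500 ng replicate 1, 9 and 8 without replicate 2, and 29 and 33 without replicate 3. They were 63 and 32, 27 and 35, and 9 and 6 without empty-vector replicates 1, 2 and 3. With fewer plasmid calls the overlap no longer passed the test without the 2500 ng replicate 1 (13 shared genes against 9.2 expected, Fisher's exact test, p = 0.141), the 2500 ng replicate 2 (17 against 14.2, p = 0.398) or empty-vector replicate 3 (15 against 10, p = 0.067). At an adjusted p under 0.01 it did not pass either (12 against 9.8, Fisher's exact test, p = 0.45). Nor did the overlap pass without the replicates numbered 3 (20 against 15.7, Fisher's exact test, p = 0.223). Without those numbered 1 or 2 only 3 and 0 plasmid genes were called (1 shared against 0.9, and 0 against 0). With so few calls these fits say little about the overlap. Without empty-vector replicate 1 the 2-sided Fisher's exact test of direction gave p = 0.00914. The AKR1C2 call with siRNA was lost without the 10 nM replicate 3 (adjusted p = 0.0706). With plasmid, FITM2 was lost without the 2500 ng replicate 2 (adjusted p = 0.0556), CPE and ERRFI1 without the 2500 ng replicates 1 or 2 or empty-vector replicate 3 (highest 0.0548 and 0.0542), ESYT1 without the 2500 ng replicate 2 or empty-vector replicate 3 (highest 0.0548) and GNPDA1 without the 2500 ng replicate 1 or empty-vector replicate 3 (highest 0.056).

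**Figure D5:**
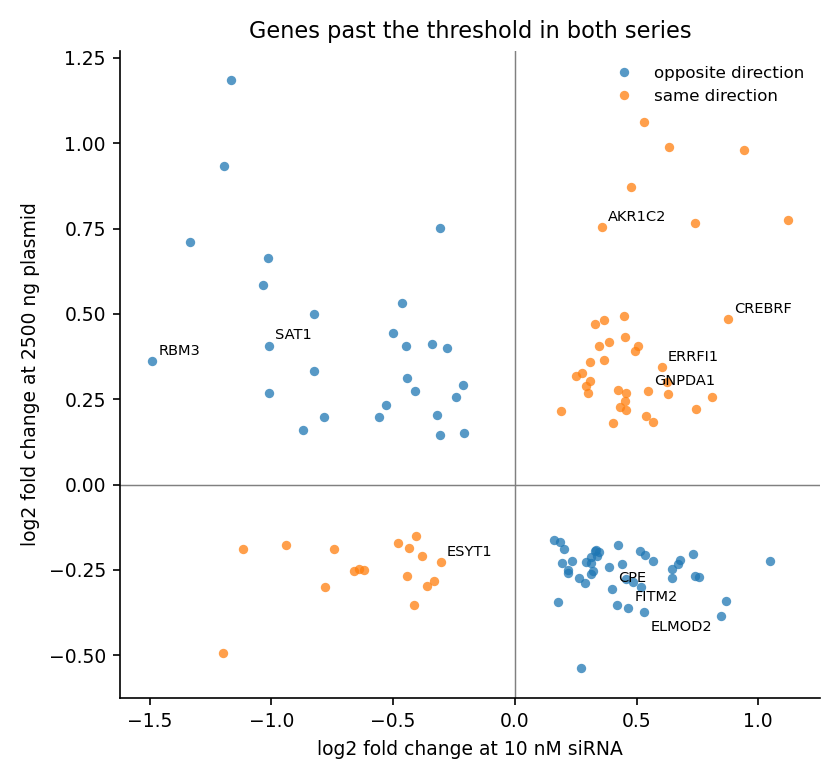
Log2 fold change at 10 nM siRNA (horizontal axis) and at 2500 ng plasmid (vertical axis), each against its own control with n = 3, for the genes past the threshold in both series except HNRNPH1; each point is a gene, coloured by direction. RBM3 lay at -1.49 and 0.36, and CREBRF at 0.88 and 0.49.

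The difference between the siRNA response at 10 nM and the plasmid response at 2500 ng was itself tested in all 36 libraries. It passed for 5087 of 18537 genes, with the siRNA value higher in 2379 and lower in 2708. HNRNPH1 differed by -4.06 ± 0.481 (adjusted p = 4.34e-07) and HNRNPH3 by 0.70 ± 0.091 (adjusted p = 4.71e-07), while HNRNPH2 (-0.19, adjusted p = 0.135), HNRNPF (0.17, 0.319) and GRSF1 (0.11, 0.282) did not pass. GALE differed by -1.72 ± 0.126, SFXN2 by -1.69, RBM3 by -1.87, TGFB3 by 1.26 and SERINC2 by 2.10, each with adjusted p of at most 1.5e-07. CREBRF, which rose in both series, differed by 0.37 (adjusted p = 0.0655).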

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

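The fits without a replicate number in every group were chosen only after the data were seen, and the other alternatives were planned. No value that passed the test changed sign. HNRNPH1 values near 0 that never passed did change sign with libraries left out, from -0.10 to 0.04 at 50 pM, from -0.09 to 0.10 at 100 pM and from -0.13 to 0.08 at 250 pM. A count was taken as the same if it lay within 1.5-fold of the main count or if both were 0. A test was taken as the same if it kept its pass status and, where it passed, its sign. Of 438 alternative values of main results 331 stayed the same in this sense, 93 moved, 5 were stronger and 9 weaker. Of 3565 for named genes and lists 3246 stayed the same, 20 were stronger and 299 weaker, 237 of the weaker ones from leaving out libraries. With DESeq2's Wald test the counts were 449 at 500 pM, 114 at 600 ng, 4 at 1000 ng and 454 at 2500 ng, with 153 genes opposite and 101 in the same direction, and HNRNPH1 passed at 1000 ng (1.36, adjusted p = 0.00495). Without the filter on low counts they were 16 at 100 pM, 28 at 250 pM, 278 at 500 pM, 203 at 600 ng, 63 at 1000 ng and 629 at 2500 ng, with 211 opposite and 121 same (2-sided Fisher's exact test of direction, p = 3.68e-08). HNRNPH1 then had adjusted p = 0.00154 at 1 nM (-0.45), 1.27e-16 at 600 ng (0.40) and 1.9e-201 at 1000 ng (1.36). The value at 1000 ng is not plausible for 3 libraries per group at 1795 ± 600 CPM. With the filter, edgeR's quasi-likelihood test gave adjusted p = 0.625 there. The p-values, counts and direction test of the unfiltered fit are therefore descriptive only, and the reason was not tested. With only the 2 groups in the fit the counts were 4 at 250 pM, 5 at 500 pM, 21 at 600 ng and 58 at 2500 ng, and HNRNPH1 had adjusted p = 0.0962 at 5 nM (-1.21), 0.105 at 10 nM (-1.20) and 0.0111 at 600 ng (0.40). With a replicate block they were 693 at 500 pM, 501 at 1 nM, 1 at 600 ng, 2 at 1000 ng and 354 at 2500 ng, with 116 opposite and 95 same (2-sided Fisher's exact test of direction, p = 0.0401). Residual correlations of same-number pairs ran from -0.2 to 0.75 in the siRNA series (64 of 84 over 0.1) and from -0.17 to 0.33 in the plasmid series (7 of 18). By residuals 20 of 24 siRNA and 7 of 12 plasmid libraries lay closest to one of their own number, a hint from the data, not the design, that siRNA libraries of a number shared variation. The rank trend with controls called 215 genes for plasmid. At an adjusted p under 0.01, 5 genes were opposite and 7 same. With an estimated correlation 0 lists passed for siRNA and 0 for plasmid, with fry 14 and 7, and with DESeq2's size factors 7 and 10, against 10 and 10. Leaving out libraries gave counts of 0 to 2 at 250 pM, 4 to 347 at 500 pM, 9 to 142 at 1 nM, 2270 to 4746 at 5 nM, 4435 to 6391 at 10 nM, 0 to 22 at 600 ng, 0 to 0 at 1000 ng and 0 to 165 at 2500 ng. It gave 255 to 1791 for the plasmid trend, 6255 to 8668 for the siRNA trend and 2879 to 5077 for the difference. HNRNPH1 ran from -1.55 to -0.86 at 5 nM, from -1.58 to -0.83 at 10 nM (adjusted p = 0.195 and 0.165 without replicate number 2 at 5 and 10 nM) and from 2.69 to 3.11 at 2500 ng, where adjusted p was 0.0714 and 0.119 without replicate numbers 1 and 2. Opposite genes numbered 0 to 69, same-direction genes 0 to 56, and lists past the test 4 to 9 for siRNA and 8 to 11 for plasmid. For each result that changed the cause was not tested.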

Other observations

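The test of HNRNPH1 reads assigned to HNRNPH3 was chosen only after the result was seen, as were the genes in this paragraph. Some genes called in both series, which no fixed list covered and no group test was run on, are given here 1 by 1. They were not tested with libraries left out. Of all genes called in both, 38 rose in both and 17 fell in both. Another 43 rose with siRNA and fell with plasmid, and 28 did the reverse. The ferritin genes FTH1 (0.37 with siRNA, 0.48 with plasmid) and FTL (0.45, 0.43) rose in both, as did TXNRD1, a thioredoxin reductase (0.39, 0.42), GCLC, which starts glutathione synthesis (0.19, 0.22), and AKR1C1, an aldo-keto reductase (0.63, 0.99). PIR (-0.825, 0.334), PTGR1 (-0.278, 0.399) and MAFG (-0.338, 0.413) instead fell with siRNA and rose with plasmid. GALNT3 (0.65, -0.27) and GALNT12 (0.76, -0.27), which start O-glycans, rose with siRNA and fell with plasmid. The oligosaccharyltransferase genes TUSC3 (0.65, -0.25) and STT3A (0.20, -0.19) and the signal recognition particle receptor gene SRPRA (0.68, -0.22) did the same. SLC35B2, a sulfate donor transporter of the Golgi (-1.12, -0.19), and PIGO, a glycolipid anchor enzyme (-0.38, -0.21), fell in both.

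The median log2 of the interferon list was 0.03 at 50 pM, 0.42 at 100 pM, 0.38 at 250 pM, 0.27 at 500 pM and 0.01 at 1 nM, with 0 members called. At 600 ng plasmid the median was -0.49 and at 1000 ng -0.15, also with 0 called. No list test was run at those doses, so no group change is claimed.

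HNRNPH3 rose at siRNA doses at which HNRNPH1 did not pass. The HNRNPH1 estimate there was wide (log2 -0.001 ± 0.355 at 250 pM), so a smaller fall is not excluded. Reads of HNRNPH1 assigned to HNRNPH3 were considered as a cause. The gain of HNRNPH3 at 250 pM exceeded the loss of HNRNPH1 by 100 ± 46.7 CPM (SE). With 3 libraries per group this margin is too imprecise to exclude that cause. Seed sites of the control siRNA in the HNRNPH3 3' UTR, which could hold it down in controls, numbered 0. A response to HNRNPH protein through splicing of HNRNPH3 stays open, as no exon counts or protein levels were available.

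More than 1 cause may lie behind the 6704 genes at 10 nM. Of the fallen genes with a searched 3' UTR 18.5% carried a seed site of the HNRNPH1 siRNA, against 14.3% of risen genes and 13.6% of genes that did not pass. Direct pairing at such sites therefore does not account for most fallen genes. The prediction for a small contribution, written beforehand, was met. Only 1 of 104 other 7-mers of the same base composition shifted genes as low or lower. The shift for the seed site was -0.04, so the values go with a small contribution. Only exact 7-mers in the 3' UTR of 1 transcript per gene were counted. Indirect changes downstream of seed pairing were not tested, so an off-target origin stays open. Replicate number 3, with the lowest HNRNPH1, was not the whole cause, since the count without it was 79.8% as large, and 4993 of the 6704 genes were called again. Its slope on the other replicates was 0.86, and replicates 1 and 2 had 0.81 and 0.88, so none reached 1. For each slope the genes were chosen by calls from the same other replicates that set the predictor, which pulls the slope below 1. The slopes therefore cannot tell whether less HNRNPH1 gave a larger response, or whether the response had saturated. GC content and length took up 2.6% of the variance of replicate 3's difference from replicates 1 and 2 at 10 nM, and 2.4% at 5 nM.

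Splits against a control and splits of the difference were fitted with only the libraries compared, so their real counts differ from those of the full fits (4614 for the difference, against 5087). With 10 splits, too few for a share under 0.05, the real split called 0 genes at 50 pM (highest other 0; 10 splits reached the real count), 0 at 100 pM (1; 10), 4 at 250 pM (22; 2), 5 at 500 pM (0; 1), 244 at 1 nM (0; 1), 3400 at 5 nM (0; 1) and 5455 at 10 nM (0; 1). For plasmid it called 21 at 600 ng (1554; 2), 0 at 1000 ng (300; 10) and 58 at 2500 ng (495; 2), and at each amount 1 other split called genes. These 3 splits put empty-vector replicate 2 with treated libraries, and their counts point to a structure of the samples whose cause stays open. Over 100 splits chance could be excluded at a share under 0.05 for the siRNA trend (8327, highest other 2473, 1 split). For the plasmid trend the share was also under 0.05 (1192, 1236, 3), but another order called more genes than the real one. For the difference in that smaller fit it was too (4614, 4124, 1). Splits of the difference could keep the true siRNA grouping, so that share does not test the plasmid response apart from the siRNA response.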
